A study of Mus musculus with 6 samples.

How the data were processed

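RNA from 6 samples of mouse myeloid cells was measured on Affymetrix Mouse Gene 2.0 ST arrays, 1 array per sample. There were 3 uninduced and 3 induced samples, and each sample was assigned to its group by its title. The values used are the log2 expression values deposited by the authors, 1 for each of 41345 transcript clusters on each array. Per the submitters' processing notes, Partek software and the mouse build mm10 were used; the software version, the background correction, the normalization and the summary method are not given in the sources used here. Because the scale of the deposited table was not stated, it was read from the values, which ran from 2.86 to 14.03 with array medians between 6.53 and 6.78, as log2 summaries of such arrays do. The interquartile ranges differed between arrays, so the deposited gene values had not been brought to 1 common distribution.

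Transcript clusters were named through GEO's platform annotation, which can be old. Of the 41345 transcript clusters, 23521 carried 1 gene symbol, 1814 carried several, and 16010 were not listed. No symbol needed updating through its Entrez identifier in the RefSeq table of mouse assembly GRCm38, the assembly also called mm10. Where 1 of the 1082 genes with more than 1 transcript cluster was tested, the cluster with the highest mean over all 6 arrays stood for it, which left 22180 genes. Among the genes past the threshold, 17 had several transcript clusters, and 7 of these had a cluster whose change ran the opposite way.

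Induced and uninduced samples were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with no covariate and no filter on dim genes, and Benjamini-Hochberg adjustment over the 22180 genes at a threshold of 0.05. Log2 fold changes are induced minus uninduced throughout. Both groups carry the letters A, B and C, but no label says that a letter marks a shared culture or day, so the letter was not in the model. A set of 35 gene lists was compared with all other genes by camera with a preset correlation of 0.01 and adjustment over the 35 lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation the adjustment gave many lists the same adjusted p of 0.497, which does not rank them. Their unadjusted camera p-values ran from 0.055 for neutrophil and granule genes to 0.312 for fibroblast and stromal genes. Fry tests whether a list's genes moved, on balance, one way, and does not compare the list with other genes. Of 751 listed gene names, 676 were found; an older name was matched through a synonym only where it was not the current symbol of another gene. A list's median was also set against the medians of 10000 random lists of equal size, matched on mean expression in 20 bins.

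The groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names Spi1 and E2f1, the 8 genes with the largest rise and the 8 with the largest fall among genes past the threshold whose groups did not overlap, up to 4 members of each list past the threshold, and up to 2 of the brightest members where none passed. All members of the lists of E2F and pocket proteins, of CDK inhibitors and of G1 cyclins may be named. No unnamed or predicted gene models fell within the top ranks.

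The alternatives tried were the letter as a block, quantile normalization, median centring, filters on dim genes at the 25th and 50th percentile, a variance trend with robust moderation, no moderation, the mean of a gene's transcript clusters, array weights, all transcript clusters, stricter thresholds, and leaving out each array in turn. Quantile normalization over the gene values alone, cyclic loess over them, and leaving out induced B and C together were added after seeing the data. As a reference for genes that these cells are not known to use, 1394 olfactory and vomeronasal receptor genes were taken as 1 group. Those receptor genes had their 95th percentile between 7.05 and 7.99 on the 6 arrays. A value below it is taken as in the range of background. Where a gene past the threshold was in that range on all 3 arrays of a group, the group's level is only a bound, and the fold is given as at least that from the mean of the percentile on those arrays, or not at all where the other group was above that range on fewer than 2 arrays.

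The gene test was checked on simulated data for this comparison, with 200 of 22180 genes changed. It recovered 5.97% of genes changed by a log2 of 0.5, 53.7% of those changed by 1 and 97.0% of those changed by 2, with 2 false calls. In the same simulation camera recovered the 1 list that had been shifted by -0.4 and called 0 of 20 unshifted lists. The simulated genes varied independently of each other and had no shift with expression level. In the real data the estimated correlation within the list of G1/S and DNA replication genes was 0.799. The simulation therefore does not show how often camera or the gene test calls falsely here. Arrays give no counts, so their number, 3 per group, limits the precision.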

Results

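Gene expression was profiled in myeloid cells of mouse fetal liver, grown in 1 ng/ml GM-CSF, a growth factor of granulocytes and macrophages. Of the 6 samples, 3 were uninduced and 3 received 1000 ng/ml doxycycline for 72 hours. The labels equate the doxycycline treatment with expression of PU.1, the ETS-family transcription factor of myeloid and B cells that Spi1 encodes. Doxycycline is a tetracycline analogue used to switch on an engineered gene, and the labels do not describe the construct. No sample had doxycycline without PU.1 induction, so in every comparison below an effect of the drug itself cannot be told apart from one of PU.1. Pairs of arrays correlated at 0.973 to 0.988 within a group and at 0.942 to 0.991 between groups, over all transcript clusters. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

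The comparison of induced with uninduced cells asks, after the title of the series, which genes move with PU.1 as cells leave the cell cycle, and whether E2f1 is lower. Among transcript clusters with 1 gene symbol, those of the formyl peptide receptor gene Fpr2 and the signalling adaptor gene Tyrobp had the largest measured rises in the induced cells. Of 18 genes of cholesterol synthesis 11 fell, and of 12 genes of glycolysis 6. Both lists were lower by camera with a preset correlation and not with an estimated one (adjusted p = 0.497 for each). Unadjusted, camera with an estimated correlation gave p = 0.082 for cholesterol and 0.0596 for glycolysis. Fry called only glycolysis (adjusted p = 0.0406, against 0.0624 for cholesterol). Transcript levels of Spi1 and E2f1 differed by small amounts that did not pass the test, and no gene of DNA replication or mitosis among those listed passed it.

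Spi1 (chromosome 2, 91082374 to 91115759 in mm10) had a log2 value of 8.80, 8.65 and 8.84 in uninduced A, B and C and of 9.13, 9.04 and 9.05 in induced A, B and C. The difference was 0.31 (SE 0.12, limma adjusted p = 0.152), or 1.24-fold, higher in 3 of 3 induced samples. Its 95% interval, which is not adjusted for the number of genes, ran from 0.036 to 0.59 (limma unadjusted p = 0.0302). Whether this transcript cluster covers the sequence of the engineered gene is not known here, so the difference may not measure how far PU.1 was induced. E2f1 (chromosome 2, 154559400 to 154569892), a transcription factor of genes for S phase entry, was at 8.83, 9.23 and 8.81 in the uninduced samples and at 8.77, 8.60 and 8.50 in the induced ones. Its difference was -0.33 (SE 0.15, adjusted p = 0.179), with a 95% interval from -0.67 to 0.0034, and -0.20 (adjusted p = 0.49) without uninduced B. Array weights, which down-weight the more variable arrays, took both past the threshold, at 0.23 (adjusted p = 0.0325) for Spi1 and -0.31 (adjusted p = 0.0185) for E2f1. But under this setting 5825 genes were called higher and 5681 lower of 22180. The weights were 4.6 for uninduced C and 3.46 for induced C, and from 0.309 to 0.932 for the other arrays, so the setting rested mostly on the C arrays. Median centring put Spi1 at 0.17 (adjusted p = 0.356). After cyclic loess, Spi1 was at 0.67 (adjusted p = 0.0915) and E2f1 at 0.01 (adjusted p = 0.966), on the other side of 0.

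**Figure D1:**
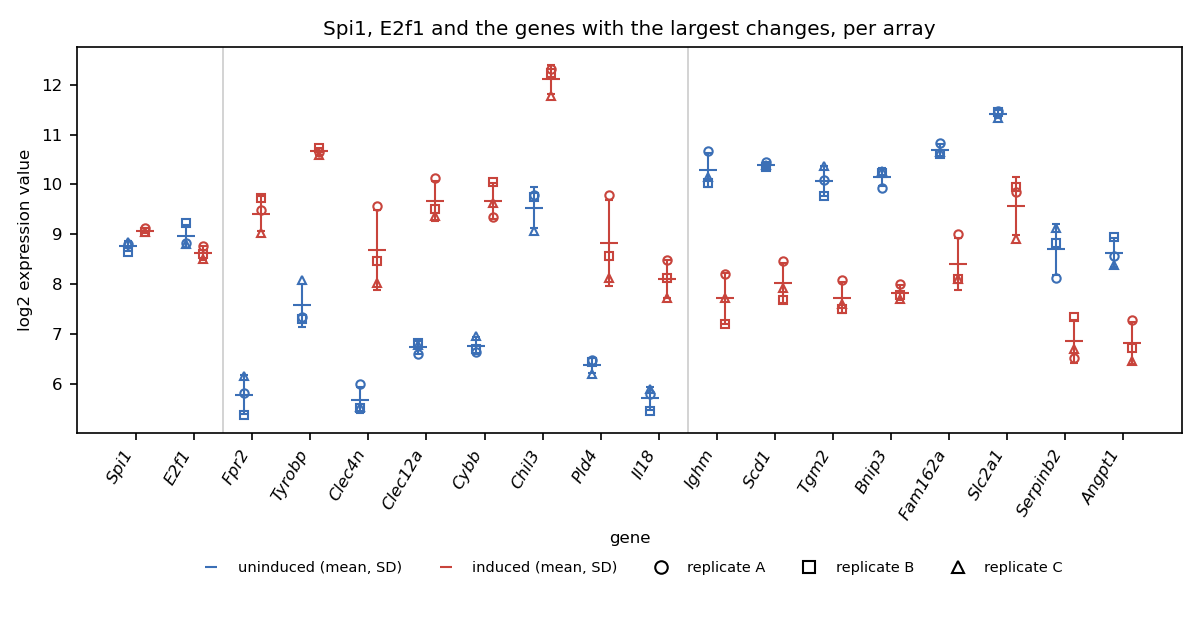
Log2 expression value (vertical axis) on each of the 6 arrays for Spi1, E2f1, the 8 genes with the largest measured rise and the 8 with the largest measured fall (horizontal axis). Open symbols are arrays A, B and C, and bars give the mean and SD of 3 arrays; for Spi1 the means are 8.76 and 9.07 and for Fpr2 5.79 and 9.42.

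Of 22180 genes, 83 were higher and 232 lower in induced cells at an adjusted p under 0.05, and 6281 had an unadjusted p under 0.05. The 3 values of one group lay above the 3 of the other for 6963 of the 22180 genes, the 315 among them. Measured log2 changes ran from 0.60 to 3.63 (median 1.13) among the higher genes and from -0.56 to -2.57 (median -0.93) among the lower ones. The higher genes made up 26.3% of the calls as deposited, and 41.3% after cyclic loess, which called 83 higher and 118 lower; 65 of the higher and 110 of the lower genes were called both ways. Leaving out 1 array at a time gave 45 to 61 higher and 47 to 93 lower genes for 5 of the arrays, but 1998 and 3535 without induced A. With induced A alone against the uninduced samples the numbers were 41 and 19.

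The largest measured rise of a gene was that of Fpr2, from 5.79 ± 0.39 to 9.42 ± 0.35 (mean ± SD, n = 3 per group). In uninduced cells Fpr2, Clec4n, Clec12a, Cybb, Pld4 and Il18 were below the 95th percentile of the olfactory and vomeronasal receptor genes on all 3 arrays. Their starting levels lay in the range of background, so their folds are given as bounds taken from that percentile, which for Fpr2 is at least 4.49-fold. Of the 83 higher genes 54 started in that range, and 24 of them stayed in it on all 6 arrays. Members of the reference group itself were among the higher genes. They included Olfr1024, Olfr1265 and Vmn1r113 (limma adjusted p = 0.039, 0.0433 and 0.0329), picked after their values were seen. Tyrobp, the adaptor of several activating receptors of myeloid cells, rose from 7.58 ± 0.44, above that range on 2 of 3 uninduced arrays, to 10.66 ± 0.07, which is 8.49-fold. The C-type lectin receptors Clec4n (dectin-2) and Clec12a rose at least 2.71-fold and 5.35-fold. Cybb, the catalytic subunit of the phagocyte NADPH oxidase, rose from 6.77 ± 0.17 to 9.67 ± 0.36, or at least 5.36-fold, and Chil3, a chitinase-like secreted protein, rose 5.96-fold to 12.11 ± 0.29. Pld4, of the phospholipase D family, and the cytokine gene Il18 rose at least 2.98-fold and 1.82-fold, Il18 to a level above the range of background on 2 of 3 induced arrays. Adjusted p-values of these 8 genes lay between 5.82e-05 and 0.00585.

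The largest measured fall of a gene was that of Ighm, which encodes the constant region of the IgM heavy chain, from 10.29 ± 0.34 to 7.71 ± 0.51, a log2 change of -2.57. That value comes from 1 of 7 transcript clusters of the gene; the other 6 changed by -0.08 to 0.57, and the mean over all 7 by -0.10 (adjusted p = 0.581). Scd1, a fatty acid desaturase, fell from 10.40 ± 0.05 to 8.03 ± 0.40 and was 5.17-fold lower. Tgm2, a transglutaminase, fell from 10.07 ± 0.30 to 7.73 ± 0.31. Bnip3, a mitophagy receptor of the mitochondrial outer membrane, fell from 10.14 ± 0.19 to 7.83 ± 0.16 (4.96-fold lower), and Fam162a, which encodes another mitochondrial protein, was 4.87-fold lower. Slc2a1, the glucose transporter GLUT1, was 3.60-fold lower at 9.57 ± 0.58 in induced cells. Serpinb2, a plasminogen activator inhibitor, and the angiopoietin gene Angpt1 were at least 1.94-fold and 1.86-fold lower, since both lay in the range of background on all 3 induced arrays. Scd1 was above that range on 2 induced arrays, and Ighm, Tgm2 and Bnip3 on 1 each. Adjusted p-values lay between 5.82e-05 for Bnip3 and 0.00764 for Serpinb2.

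Genes reported elsewhere as regulated by PU.1 were higher as a list by camera, with a median change of 0.20 (camera adjusted p = 0.00011; adjusted p = 0.497 with an estimated correlation; fry adjusted p = 0.0221). Of 34 measured members 9 rose and 0 fell (11 rose and 0 fell when adjusted over the list alone; 13 and 3 at an unadjusted p under 0.05). Besides Cybb and Tyrobp, Mpeg1, a pore-forming protein of macrophages, rose at least 1.37-fold from the range of background to above it on 2 of 3 induced arrays, and Lyz2, lysozyme, by 1.43 (SE 0.15). The median was 0.06 after median centring and 0.36 after cyclic loess (camera adjusted p = 4.81e-12; adjusted p = 0.256 with an estimated correlation).

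Among 37 macrophage markers 7 rose and 1 fell, or 13 and 2 when adjusted over the list alone. Adgre1, which encodes F4/80, rose from 6.68 ± 0.23 to 8.84 ± 0.54, and Mrc1, the mannose receptor, rose from 6.47 ± 0.34 to 8.40 ± 0.33. Both started in the range of background on all 3 uninduced arrays, so these are rises of at least 3.02-fold and 2.21-fold. The member that fell, chosen after its value was seen, was the scavenger receptor Cd36 (adjusted p = 0.0189), which was above that range on 1 of the 6 arrays only, so no size is given. The list's median change was 0.25 (camera adjusted p = 0.000143; adjusted p = 0.497 with an estimated correlation; fry adjusted p = 0.0369), and 0.11 after median centring. Neutrophil and granule genes held 6 of 25 members that rose (9 rose and 1 fell when adjusted over the list alone), among them the calcium-binding protein gene S100a9 at 1.53 (SE 0.20). Mmp8, a collagenase, and Ltf, lactoferrin, rose from the range of background by at least 2.90-fold and 1.94-fold, Ltf to above it on 2 of 3 induced arrays. The list's median was 0.23 (camera adjusted p = 0.000465; adjusted p = 0.497 with an estimated correlation; fry adjusted p = 0.0221), and 0.09 after median centring and 0.12 without uninduced B. The call of Ltf ended when uninduced A, uninduced B or induced C was left out, at measured changes between 2.00 and 2.07.

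Pattern recognition receptors, which sense microbes, had 4 members that rose and 1 that fell of 23 (8 and 2 when adjusted over the list alone). Tlr8, an endosomal receptor for RNA, rose at least 2.41-fold from the range of background, beside Clec4n and Clec12a. Clec4a2 passed the test too (adjusted p = 0.0011), but lay in that range on all 6 arrays, so no size is given. Clec4e, chosen after its value was seen, fell (adjusted p = 0.0225) to a level above that range on 1 of 3 induced arrays. The list's median was 0.18 (camera adjusted p = 0.00895; adjusted p = 0.497 with an estimated correlation), and 0.04 after median centring and 0.28 without induced C. Of 22 haematopoietic growth factor receptors Il6ra (0.89, SE 0.14) and Csf3r, the G-CSF receptor, rose, or 3 when adjusted over the list alone. Csf3r was above the range of background on 1 of the 6 arrays only, so no size is given. Their list was not called (median 0.04, camera adjusted p = 0.653), but was after cyclic loess (median 0.05, camera adjusted p = 0.0408; adjusted p = 0.272 with an estimated correlation). The calls of Il6ra and Csf3r ended without uninduced A or induced C, at measured changes of 0.83 to 0.99, that of Il6ra also without uninduced C (0.84) or induced B (0.89), and that of Csf3r without uninduced B (0.82). Of the 26 inflammatory cytokines and chemokines only Il18 rose and 0 fell (list alone 1 and 0; 4 and 6 at an unadjusted p under 0.05); the median was -0.04, the mean 0.01 and the camera adjusted p 0.900, in the lower direction. Interferon-stimulated genes went both ways, with Oas2 higher (above the range of background on 1 of the 6 arrays only, so with no size given) and Ifitm3 lower (-1.21) among 23 (list alone 3 and 3; median 0.12, camera adjusted p = 0.427). The call of Ifitm3 ended without induced C (-1.15), and that of Oas2 without uninduced A, B or C or induced C (measured changes of 0.82 to 0.93) and after cyclic loess (0.73, adjusted p = 0.0686).

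Of 18 measured cholesterol biosynthesis genes 11 fell and 0 rose, and all 18 fell when adjusted over the list alone, as at an unadjusted p under 0.05. After cyclic loess all 18 stayed below 0, with 3 past the threshold. Lanosterol synthase, Lss, went from 9.50 ± 0.22 to 7.93 ± 0.60 (above the range of background on 1 of 3 induced arrays), a change of -1.57 (SE 0.26), Insig1, a sterol-regulated membrane protein, by -1.11 (SE 0.18), Hsd17b7 by -1.09 (SE 0.16) and Dhcr7, of the last step to cholesterol, by -0.87 (SE 0.16). The median was -0.85 as deposited (camera adjusted p = 5.35e-14; adjusted p = 0.497 with an estimated correlation; fry adjusted p = 0.0624) and -0.51 after cyclic loess (camera adjusted p = 2.63e-13; adjusted p = 0.256 with an estimated correlation), with -0.54 in induced A, -1.10 in induced B and -0.98 in induced C. Each of these 4 calls ended without uninduced A and also without induced C, at changes between -1.46 and -0.89 without uninduced A and between -1.40 and -0.90 without induced C. Insig1, Lss and Dhcr7 also lost theirs without uninduced B (-1.58 to -0.79) or induced B (-1.40 to -0.73), and Dhcr7 without uninduced C (-0.94) or after cyclic loess (-0.50, adjusted p = 0.0812).

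Of 12 measured glycolysis genes 6 fell and 0 rose (11 and 0 when adjusted over the list alone and at an unadjusted p under 0.05). Beside Slc2a1, the lactate transporter Slc16a3 fell by 1.29 (SE 0.15), and the phosphofructokinase subunits Pfkp and Pfkl were at -1.27 (SE 0.18) and -1.76 (SE 0.28). The median was -0.90 (camera adjusted p = 4.87e-10; adjusted p = 0.497 with an estimated correlation; fry adjusted p = 0.0406) and -0.69 after cyclic loess (camera adjusted p = 3.58e-10; adjusted p = 0.256 with an estimated correlation), with -0.55 in induced A, -1.04 in induced B and -1.18 in induced C. Pfkp lost its call without uninduced A (-1.26), and Pfkl without uninduced A, induced B or induced C (-1.66 to -1.55).

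No measured cell cycle gene of the 2 lists fixed for it passed the gene test. All 49 genes of G1/S and DNA replication had a change below 0 as deposited, and 30 after cyclic loess, with 0 past the threshold by limma, 0 when adjusted over the list alone, and 24 at an unadjusted p under 0.05. Pcna, the sliding clamp of DNA replication, was at 11.87 ± 0.11 and 11.68 ± 0.19, and Rrm1, a ribonucleotide reductase subunit, at 11.29 ± 0.24 and 10.89 ± 0.25. The median was -0.38 (camera adjusted p = 8.04e-09; adjusted p = 0.497 with an estimated correlation; fry adjusted p = 0.206), made up of -0.10 in induced A and -0.51 in both induced B and induced C. Without uninduced B it was -0.24. All 48 mitosis genes were below 0 too, and 23 after cyclic loess (1 fell when adjusted over the list alone, 22 at an unadjusted p under 0.05), with a median of -0.33 (camera adjusted p = 9.39e-09; adjusted p = 0.497 with an estimated correlation; fry adjusted p = 0.198). Their median was -0.04 in induced A, -0.53 in induced B and -0.48 in induced C. The proliferation marker Mki67 was at -0.10 (SE 0.12) and Ccnb2 at -0.23 (SE 0.13), neither past the threshold. After cyclic loess the medians were -0.08 (camera adjusted p = 0.305) and 0.01 (camera adjusted p = 0.723, in the lower direction).

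The 13 E2F and pocket protein genes all lay below 0 as deposited, and 8 after cyclic loess, with 0 past the threshold by limma, 0 over the list alone and 8 at an unadjusted p under 0.05. E2f3 was at -0.60 (SE 0.23), the pocket protein genes Rbl2 at -0.57 (SE 0.18) and Rb1 at -0.48 (SE 0.13), while E2f7 and E2f8 were at -0.18 (SE 0.17) and -0.10 (SE 0.17), and at 0.18 and 0.27 after cyclic loess. Their median of -0.38, which was -0.19 in induced A (camera adjusted p = 0.000465; adjusted p = 0.497 with an estimated correlation) became -0.11 after cyclic loess (camera adjusted p = 0.396). Of 12 CDK inhibitors and antiproliferative genes Cdkn1a, which encodes p21, fell from 11.42 ± 0.14 to 10.33 ± 0.44, a change of -1.09 (SE 0.20, adjusted p = 0.0289), and 2 fell when adjusted over the list alone. Its call ended after cyclic loess (-0.78, adjusted p = 0.143), and without uninduced A, B or C or induced C (-1.15 to -0.86). Cdkn1b was at -0.51 (SE 0.31), Cdkn2a at 0.28 (SE 0.14) and Cdkn2c at -0.14 (SE 0.15), none past the threshold, and the list was not called (median -0.12, camera adjusted p = 0.106). Among the 6 G1 cyclins and CDKs, 0 passed over all genes or over the list alone and 2 had an unadjusted p under 0.05; Ccnd3 was at -0.39 (SE 0.14), Cdk2 at -0.38 (SE 0.15) and Cdk6 at -0.18 (SE 0.14), with a median of -0.23 (camera adjusted p = 0.102).

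The arrays of induced B and C had the narrowest spread of values, and that of uninduced B the widest. Interquartile ranges were 1.88 and 1.93 in induced B and C and 2.29 in induced A. In uninduced A, B and C they were 2.31, 2.76 and 2.41. Relative to the uninduced mean, the brightest 30% of genes had a median of -0.46 in induced B, -0.42 in induced C and -0.11 in induced A, and the dimmer 50% had 0.24, 0.21 and 0.06. Olfactory and vomeronasal receptor genes were at 0.45, 0.29 and 0.06 in the same order. Uninduced B lay on the other side, at 0.16 for the brightest 30% and -0.07 for the dimmer 50%. Part of the fall of bright genes between the groups therefore comes from that array. Over all genes the median change was 0.06 as deposited and -0.08 after median centring, a shift of more than 0.1 that applies to each change above.

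**Figure D2:**
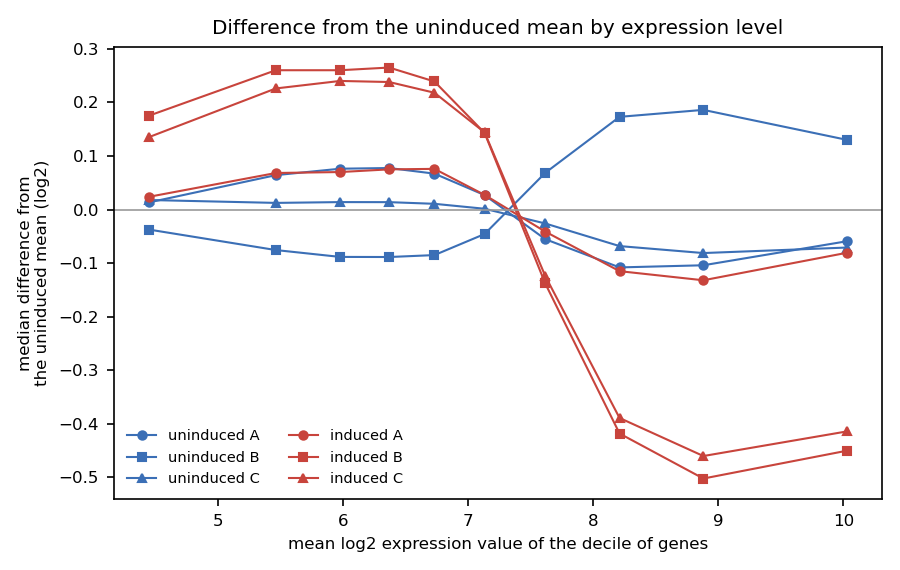
Median difference from the uninduced mean (log2, vertical axis) over 10 equal bins of genes ordered by mean log2 expression value (horizontal axis), 1 line per array. Induced B and C lie at 0.26 and 0.23 at a mean level of 5.46 and at -0.50 and -0.46 at a mean level of 8.88, where induced A is at -0.13 and uninduced B at 0.19.

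Oxidative phosphorylation subunits had 24 of 24 members below 0 (17 after cyclic loess) and a median of -0.35 (0 past the threshold by limma or over the list alone, 8 at an unadjusted p under 0.05; camera adjusted p = 5.15e-05; adjusted p = 0.497 with an estimated correlation), -0.02 in induced A and -0.11 after cyclic loess (camera adjusted p = 0.162). Ribosome biogenesis genes had 27 of 28 below 0 (19 after cyclic loess) and a median of -0.37 (0 past the threshold or over the list alone, 8 unadjusted; camera adjusted p = 6.8e-05; adjusted p = 0.522 with an estimated correlation), -0.01 in induced A and -0.04 after cyclic loess (camera adjusted p = 0.635). Npm1 and Ncl, abundant nucleolar proteins, were at -0.28 (SE 0.19) and -0.45 (SE 0.20). In the integrated stress response, 1 of 26 ATF4 targets fell (3 over the list alone), Ddit4, which inhibits mTORC1, from 9.16 ± 0.12 to 7.37 ± 0.27 (above the range of background on 1 of 3 induced arrays). The median was -0.36 (camera adjusted p = 7.43e-05; adjusted p = 0.497 with an estimated correlation), -0.16 in induced A and -0.10 after cyclic loess (camera adjusted p = 0.0271; adjusted p = 0.464 with an estimated correlation). The mitochondrial proteases Lonp1 (-1.14, SE 0.22) and Afg3l2 (-0.91, SE 0.16) fell among 9 genes of the mitochondrial unfolded protein response (2 over the list alone; median -0.48, camera adjusted p = 0.000236; adjusted p = 0.497 with an estimated correlation), whose median was -0.08 in induced A, -0.70 in induced B and -0.78 in induced C. After cyclic loess it was -0.20 (camera adjusted p = 0.0253; adjusted p = 0.554 with an estimated correlation). Lonp1 and Afg3l2 lost their calls without uninduced A, uninduced B, induced B or induced C, Lonp1 at -1.10 to -0.92 and Afg3l2 at -0.97 to -0.80, and Afg3l2 also without uninduced C. After cyclic loess Lonp1 lost its call too (-0.77, adjusted p = 0.09), and Afg3l2 was at -0.55 (adjusted p = 0.033). Targets of p53 had a median of -0.36 (camera adjusted p = 0.000236; adjusted p = 0.497 with an estimated correlation), where Cdkn1a and the death receptor gene Tnfrsf10b (at least 1.26-fold, to the range of background) fell of 19, or 7 over the list alone. The list's median was -0.17 in induced A and -0.23 after cyclic loess (camera adjusted p = 0.000543; adjusted p = 0.272 with an estimated correlation). Tnfrsf10b lost its call without induced B or induced C, at measured changes of -1.19 and -1.21.

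Markers of other cell types and of antigen presentation were mostly dim and lay above 0 in the induced samples, as the receptor genes did. Medians were 0.24 for hepatocyte genes (14 of 14 above 0), 0.23 for B cell genes (14 of 14), 0.21 for T and NK cell genes (18 of 19), 0.22 for dendritic cell markers (15 of 17), 0.27 for MHC class II presentation (9 of 10) and 0.18 for fibroblast and stromal genes (14 of 16). Median centring brought them to between 0.04 and 0.13 and ended the call of the last (camera adjusted p = 0.108). Camera adjusted p-values of these 6 lists lay between 0.00784 and 0.0352 and the adjusted p = 0.497 with an estimated correlation was the same for each. No member passed over all genes by limma, and over the list alone 1 gene of MHC class II presentation did, with 1 to 6 members of each list higher at an unadjusted p under 0.05. After cyclic loess none of the 6 lists was called, with adjusted p-values from 0.225 to 0.425 and, for example, 10 of the 14 hepatocyte and 10 of the 14 B cell genes above 0. Apoa1 and Krt8 of the hepatocyte list were at 0.29 (SE 0.17) and 0.11 (SE 0.12), and the B cell regulator Pax5 at 0.11 (SE 0.15).

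Lists without a call included stem and progenitor genes (median 0.01, mean -0.04, camera adjusted p = 0.787 in the lower direction), where Myb was at -0.20 (SE 0.17) and Myc at -0.43 (SE 0.17). Myeloid transcription factors had a median of -0.03 (camera adjusted p = 0.688), with Fli1 at -0.26 (SE 0.13) and Cebpe at -0.33 (SE 0.18). Mast cell and basophil markers were at 0.16 (camera adjusted p = 0.105), erythroid genes at 0.10 (0.850), megakaryocyte and platelet genes at 0.14 (0.345) and endothelial genes at 0.03 (0.900), in medians with the camera adjusted p in brackets. Immediate early genes had a median of -0.30 (camera adjusted p = 0.0624), apoptosis regulators of -0.17 (0.212) and replication-dependent histones of -0.17 (0.615). After cyclic loess, again without a call, 8 of these medians lay on the other side of 0: immediate early genes at 0.04, apoptosis regulators at 0.06, histones at 0.09, myeloid transcription factors at 0.03, stem and progenitor genes at -0.07, erythroid genes at -0.04, megakaryocyte and platelet genes at -0.05 and endothelial genes at -0.02. Lysosome genes, at -0.07 as deposited (camera adjusted p = 0.515), were higher after cyclic loess at 0.19 (camera adjusted p = 0.00169; adjusted p = 0.256 with an estimated correlation), with 0 members past the threshold.

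**Figure D3:**
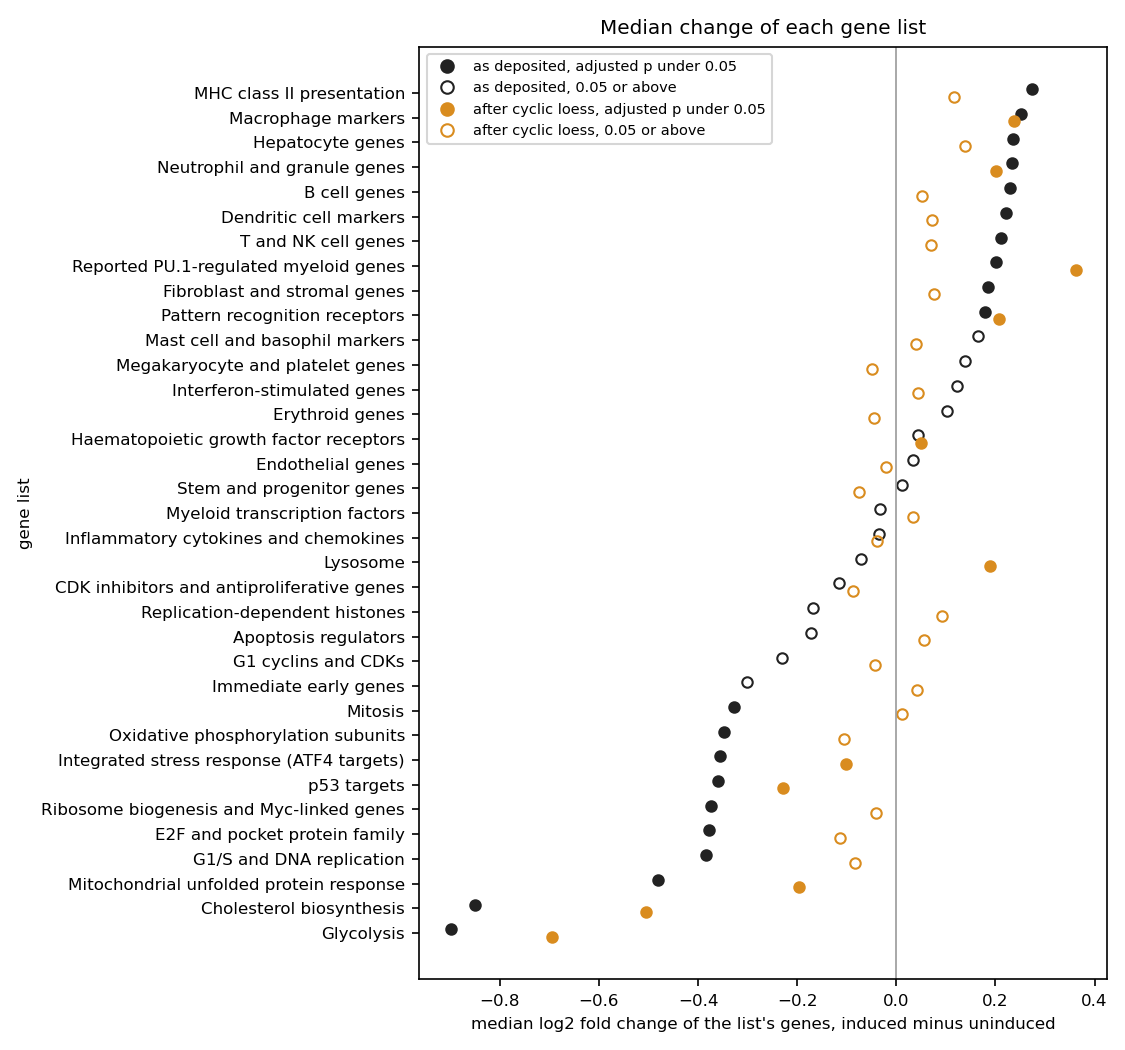
Median log2 fold change, induced minus uninduced (horizontal axis), of the genes of each of the 35 lists (vertical axis), as deposited in black and after cyclic loess in orange. Filled points have a camera adjusted p under 0.05: 20 as deposited and 11 after cyclic loess, 9 of them in the same direction both times, and 0 with an estimated correlation, where the lowest adjusted p was 0.497 as deposited and 0.256 after cyclic loess.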

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

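Of the tests in this part, those of the level-dependent pattern and of a fall of cell cycle genes beyond other genes were chosen only after the result was seen, while the comparison of the cell cycle lists with matched random lists and the count of splits were not.

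Transcript clusters that the probe annotation does not list entered no comparison of genes, and 5 of the 16010 were higher in induced cells in a fit of all transcript clusters, with 9 lower. The largest rise was that of cluster 17299101, from 7.71 ± 0.43 to 11.30 ± 0.15 (SD, n = 3 per group; log2 change 3.64, adjusted p = 0.00385), followed by cluster 17549898 (adjusted p = 0.00898), which rose to 9.42 ± 0.44 from 6.27 ± 0.47, a mean in the range of background. What they measure is not known here, and no explanation was tested.

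Among the 10 splits of the 6 arrays into 3 and 3, the real one gave 315 genes past the threshold and the highest of the others 0, so 1 split gave as many. Too few splits exist for a share under 0.05.

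The G1/S and mitosis genes were all lower on average in induced cells as deposited, but so were most bright genes. Among 10000 random lists matched on expression, the median of the G1/S list lay at percentile 3.73 and that of the mitosis list at percentile 51.4, both inside the central 95%, so an array-wide drop of bright genes may account for their size. After cyclic loess the unadjusted camera p was 0.157 for the G1/S list and 0.599 for the mitosis list, which leaves open whether either fell beyond genes of like level. In induced A alone, which is 1 array, the mitosis median was -0.0366, nearer 0 than the -0.0989 of matched random lists. The G1/S median there was -0.101, against -0.098 for matched random lists. The array-wide drop of bright genes may itself be biological. The brightest 30% of genes had a median of -0.46 in induced B and -0.42 in induced C. In induced A it was -0.11, near the -0.09 of uninduced A, so the drop did not go with induction in every sample. In uninduced B it was 0.16, which adds to the difference between the groups.

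In induced B and C dim genes were higher and bright genes lower, and induced A showed little of it. A scaling that depends on level alone is argued against: at levels from 7 to 9, 123 receptor genes had a median of 0.638 in induced B and C (95% bootstrap interval 0.598 to 0.715), while 7509 other genes of that level were at -0.28. The interval is over genes on these 2 arrays and does not measure the spread between arrays. A weaker specific signal in labelling or hybridization could raise probes of unused genes, whose median was 0.452 in induced B, but less messenger RNA in the cells' total RNA would do the same. The 2 cannot be told apart, since no value here measures the messenger RNA content, and PU.1 induction itself also stays open as untested.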

How the results depend on the processing

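Quantile normalization over genes, cyclic loess and leaving out induced B and C were chosen after seeing the data. Where the same value holds under several settings it is given once, and the cause of each change was not tested unless stated. Counts of higher and lower genes were 174 and 425 with the replicate letter as a block, 46 and 153 after median centring, 5825 and 5681 with array weights, 51 and 94 at 2-fold or more, 43 and 55 at an adjusted p under 0.01, 36 and 44 over all transcript clusters, and 41 and 19 with induced B and C left out, where 1 induced array is assumed to vary like the uninduced ones. Without variance moderation they were 0 and 0, with 3492 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.107. Lower genes numbered 353 with the 50th percentile filter, which leaves fewer genes to adjust for, 108 after quantile normalization over genes and 118 after cyclic loess. Leaving out 1 array gave 45 to 1998 higher and 47 to 3535 lower genes, the top values without induced A. The stricter thresholds give fewer by construction.

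Same-letter arrays deviated together for C (correlation 0.416) but not for A (-0.312) or B (-0.278). Induced A correlated best with uninduced A (0.991), above every pair within a group, while induced B correlated less with uninduced B (0.942) than with uninduced A (0.969). These deviations include the array-wide shift of bright and dim genes, so they cannot show whether a letter marks a shared culture. As no label says that it does, the letters are not taken as pairs. The block changed no call of Spi1, E2f1 or the 6 primary lists. It added those of Ccng2 (-0.75, adjusted p = 0.0461) and of the immediate early list (adjusted p = 0.0171), and ended that of the fibroblast list (adjusted p = 0.0555), and no other named or list call changed. Array weights took Spi1 (0.23, adjusted p = 0.0325) and E2f1 (-0.31, adjusted p = 0.0185) past the threshold, under a setting that called most genes. Over all alternatives the adjusted p of Spi1 otherwise lay between 0.0915 and 1.00, and that of E2f1 between 0.0815 and 1.00. E2f1 turned to 0.00291 (adjusted p = 0.992) after quantile normalization over genes and to 0.0113 (adjusted p = 0.966) after cyclic loess. Under these 2 settings the G1/S list lost its call at medians of -0.0978 and -0.0834, the mitosis list at -0.0153 and 0.0108, and the E2F list at -0.143 and -0.114; with induced B and C left out the mitosis list did so at -0.0366. With an estimated correlation the G1/S (-0.383), mitosis (-0.328), E2F (-0.378), macrophage (0.251) and PU.1 (0.202) lists kept their medians and lost their calls, and fry did not call the first 3. Without uninduced B the G1/S median was -0.239 and E2f1 at -0.200, and the medians were -0.175 for ribosome biogenesis and -0.231 for ATF4 targets; quantile normalization over all transcript clusters gave -0.182 for G1/S, -0.134 for mitosis and -0.120 for E2f1. Median centring, which lowers every change alike, brought the PU.1 list to 0.0611, the macrophage list to 0.110 and Spi1 to 0.171.

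The lysosome list turned higher after quantile normalization over genes (0.131), cyclic loess (0.190) and without induced B and C (0.0766), where ribosome biogenesis genes (median -0.00737, higher by camera) and histones (0.179) turned too. Cholesterol, glycolysis, PU.1, macrophage and neutrophil lists kept their direction and their call by camera with the preset correlation under every normalization, filter and left-out array tried. None of these 5 was called with an estimated correlation (adjusted p = 0.497 as deposited), and fry did not call cholesterol (adjusted p = 0.0624). Of the named genes, median centring ended the calls of Cdkn1a, Il6ra, Csf3r, Oas2, Lss, Dhcr7, Afg3l2, Lonp1 and Tnfrsf10b (adjusted p-values of 0.053 to 0.0962). Il6ra, Csf3r and Oas2 were then at 0.71 to 0.80. The others lay at -1.71 to -1.01, each further below 0 than as deposited. Both quantile normalizations ended those of Cdkn1a, Oas2 and Lonp1, and the one over genes also those of Lss and Dhcr7. With induced B and C left out, 1 induced array remained. Il6ra, Csf3r and Oas2 were then at 1.02, 0.91 and 1.07, and Cdkn1a and Tnfrsf10b at -1.038 and -1.015. Lss was at -0.88, Dhcr7 at -0.64, Lonp1 at -0.62 and Afg3l2 at -0.61. Dim genes such as Clec4a2, which stayed below the 95th percentile of receptor genes on all 6 arrays, are limited by signal over background, and of the dim filters only that at the 50th percentile leaves named genes, Gadd45g and Ccnd2, without a value.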

Other observations

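The list of hypoxia-regulated genes below was drawn up after Bnip3, Fam162a and Slc2a1 had been seen among the largest falls, and leaves those out; of its tests, the one on mitochondrial stress was chosen only after the result was seen.

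Genes known to be induced by hypoxia through the HIF transcription factors were lower in the induced cells. Of 27 such genes that no fixed list held, 24 were measured, 10 fell and 0 rose (16 and 0 when adjusted over the list alone and at an unadjusted p under 0.05), and 22 lay below 0. Plod1, a collagen lysyl hydroxylase, fell by 1.24 (SE 0.16) to a level above the range of background on 2 of 3 induced arrays, Gys1, glycogen synthase, by 1.12 (SE 0.17), Ero1a, an oxidase of protein folding, by 1.11 (SE 0.14) and the cytokine gene Mif by 1.08 (SE 0.17). Pdk1, which limits entry of pyruvate into the mitochondrial citric acid cycle, fell too, with a change of -1.13 (SE 0.18, adjusted p = 0.0147). Its level was above that range on 1 of 3 induced arrays only. These were chosen after their values were seen. Vegfa, a classical target, was at -0.79 (SE 0.20, adjusted p = 0.0838), while Car9 showed no call (adjusted p = 0.734) and was above that range on 1 induced array only.

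A hypothesis is that the HIF programme was less active in induced cells. A drop of bright genes that depends on level alone is argued against as the whole source. The list's median of -0.67 lay at percentile 0 of 10000 random lists matched on level, whose median was -0.26. Receptor genes and other genes of like level moved apart in induced B and C, and the random lists draw from both. They also do not keep the correlation between genes. A larger drop shared by all genes in use was therefore not tested. After cyclic loess the list was still lower, at a median of -0.33, with 4 members past the threshold. Its unadjusted camera p was 4.56e-10, or 0.0125 with an estimated correlation. These p-values cannot be set beside the adjusted ones of the fixed lists. They were not adjusted over those lists, and this list was drawn up after related genes were seen to fall. Doxycycline can itself impair mitochondrial translation and so might shift metabolism. But ATF4 targets, which respond to such stress, were lower rather than higher after cyclic loess (unadjusted camera p = 0.00773, or 0.146 with an estimated correlation). That p leaves it open, as no sample had doxycycline without PU.1 induction, and differences in culture density or oxygen were not tested.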
